A study of Mus musculus with 20 samples.

How the data were processed

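Total RNA of single livers of TCPOBOP-treated mice was labelled with Cy5 and hybridized against a Cy3-labelled pool of 6 vehicle-treated livers of the same genotype, per the labels. Groups and replicate numbers were taken from the sample titles. The deposited scanner tables hold, per the file headers, the median foreground intensity and local background intensity of each spot in the red and green channels, with background SDs, and the percent of saturated pixels per spot. These intensities are not normalized; the image software version and the rule by which spots were flagged are not given in the sources used here. The authors' value table holds log2 ratios per probe. Set against the log2 ratios of the same array's deposited intensities, its columns had Pearson correlations of 0.75 to 0.997 across mouse probes and slopes of 0.53 to 1.01. The direction was taken as treated over pool and the scale as log2, although slopes of 0.53 to 0.88 in CARKO leave the scale there open. Its centring differs between genotypes and stays unknown: the column medians over mouse probes were −0.93, −1.02, −0.85, −0.89, 0.65 and 0.64 for WT 1 to 6; −0.02, −0.004, −0.05, −0.28, −0.52 and 0.04 for CARKO 1 to 6; 0.23, −0.27, 0.01 and 0.27 for PXRKO 1 to 4; and −0.09, −0.26, −0.61 and −0.45 for CARPXRKO 1 to 4. The medians split within WT as well, between WT 1 to 4 and WT 5 and 6, and counts and SEs from this table that involve WT carry this split. The medians of the calibration control spots were −0.12 to 0.025 in WT and −0.11 to 5.0e-04 in CARPXRKO. In CARKO they were −0.89 to −0.25 and in PXRKO −0.57 to −0.28. A difference of centring on these spots therefore does not account for the split within WT. This table was used as an alternative only.

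Each array had 578 spots in 2 blocks, with 120 mouse probes at 3 spots and 218 control and other spots. Intensities were background-corrected with normexp (offset 50) over all spots in limma 3.58.1 (R 4.3.3). Log2 ratios were normalized by global loess within each array with control and flagged spots at weight 0. Flagged spots were then left out, from 0 to 247 per array with a median of 146.5, and saturated spots were kept. The spots of a probe were averaged. The 82 probes with a value on at least 3 arrays of every genotype were tested, and 38 were not. A spot counted as well above background when its foreground exceeded the local background by more than 2 background SDs, and a probe when most of its spots did so, flagged spots counting against it. A bound in place of a fold was computed from single-channel values after loess and Aquantile normalization, as the mean Cy5 value minus the mean of, per array, the higher of the probe's own Cy3 value and the lowest Cy3 value among probes well above background.

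One linear model with a mean log ratio per genotype was fitted to the 20 arrays with lmFit and eBayes, so that the genotypes shared an estimate of the spread (3.12 prior and 16 residual degrees of freedom). Each genotype mean was tested against 0, and 5 differences between genotypes were tested. The p-values were adjusted by Benjamini-Hochberg over the 82 probes of a comparison, with a threshold of 0.05. The pool is the control RNA and counts as 1 control sample per genotype. The design, the alternatives and the rule for named probes were fixed before the data were examined. That rule took the 12 largest rises and 12 largest falls past the threshold per response, the 6 largest either way per difference, and a list of genes by symbol. As the files do not pair probe identifiers with symbols, the text names only the first 2 rises and the first 2 falls per comparison. The probes drawn in the figures were picked after the responses had been seen. The tests of gene lists, the values of the knocked-out genes and the mean over probes of a gene were therefore not run.

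The protocol text of 4 arrays (WT 3, WT 5, CARKO 3 and CARPXRKO 3) describes the vehicle pool for the treated channel. On CARPXRKO 3 the pool's genetic background also names PXR deficiency alone, while its source names both receptors. On all 20 arrays the 4 pairs of ratio control spots had their odd-numbered member lower than their even-numbered one. These are control spots, so their order does not show which liver RNA carried which dye. The dye orientation was taken as common to all arrays because the dye labels state it. All pairs of arrays within WT and within CARPXRKO correlated positively across probes (lowest 0.55 and 0.50). This argues against a reversal of WT 3, WT 5 or CARPXRKO 3 alone, as far as no shared dye bias makes them alike. Pairs within CARKO went down to −0.08, so the orientation of CARKO 3 rests on its label. The unnormalized mean log2 ratio of the odd-numbered members differed with genotype. It was −3.08 to −2.06 in WT, −2.94 to −1.89 in CARKO, −2.52 to −0.33 in PXRKO and −1.04 to −0.74 in CARPXRKO. Spot coordinates place odd replicates in an upper and even replicates in a lower slide position in every genotype (10 arrays each).

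The alternatives were no background correction, background subtraction, median centring, print-tip loess, loess through the calibration controls (span 0.7), scale normalization between arrays, the authors' table, a filter on dim probes (1.5 times background), trended and robust eBayes, array weights, only the groups compared, a replicate block, removal of the 4 arrays with conflicting text, removal of each array in turn and a fold of at least 1.5. Flagged spots kept, slide position as a block or alone, an inferred slide, removal of CARKO 1 and CARKO 5, and a loess without the probes that rose in WT were added after the data had been seen. The pipeline was tested on simulated data at the level of spots, with 24 of 82 probes changed in WT in each of 20 simulations. For the WT response it recovered 80.6% of changes of 0.50 on the log2 scale, 95.6% of changes of 1 and 100% of changes of 2, with 4.12% false calls. For CARKO minus WT it recovered 58.1%, 90.0% and 98.8%, with 3.66% false calls. In simulated CARPXRKO arrays without a change it made 0 false calls on average. The simulated noise was drawn for each array apart, with no pool or dye effect shared by the arrays of a genotype. These false calls therefore leave out errors from a shared pool or a dye bias. The other comparisons were not simulated apart.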

Results

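Liver RNA of TCPOBOP-treated mice was compared with RNA of vehicle-treated mice of the same genotype on dual-colour Sterolgene arrays. TCPOBOP is an agonist of the mouse constitutive androstane receptor (CAR), a nuclear receptor that, with the pregnane X receptor (PXR), controls genes of drug metabolism. Mice received 10 mg/kg TCPOBOP, or 5% DMSO in oil, and livers were taken after 12 h. Each of 20 arrays held 1 treated liver (Cy5) against a pool of 6 vehicle livers of its genotype (Cy3), and each genotype had 1 pool. The arrays comprised 6 wild type (WT), 6 CAR-deficient (CARKO), 4 PXR-deficient (PXRKO) and 4 CAR and PXR deficient (CARPXRKO) livers. The questions, per the series title and design, were which responses occurred in each genotype and how they differed between genotypes.

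Each array carried 120 mouse probes at 3 spots each, of which 82 gave a value on at least 3 arrays of every genotype and were tested. The files do not pair the probe identifiers with gene names, so the CAR and PXR transcripts and the gene lists fixed in advance were not examined, and at most 2 identifiers that rose and 2 that fell are named per comparison. The median Cy5 signal of the mouse spots ranged from 226 to 987 intensity units over the 20 arrays, against median local backgrounds of 45.5 to 203. The median Cy3 signal ranged from 403.5 to 1136, against backgrounds of 121 to 507.5. Between 43 and 103 probes per array lay well above background in Cy5, and between 35 and 94 in Cy3. By genotype, the Cy3 numbers were 74 to 89 in WT, 65 to 94 in CARKO, 50 to 69 in PXRKO and 35 to 73 in CARPXRKO. This difference in detection cannot be told apart from genotype. The number of arrays limits the precision. The responses are log2 ratios of treated over pool, given as mean ± SD over arrays, and their tests leave out the spread between control animals. Dyes were not swapped, so a dye bias specific to a probe stays in each response and cancels, if shared, in the differences between genotypes. An error of a genotype's single pool does not cancel in these differences, and their SEs and p-values leave it out.

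In wild type livers, 20 of 82 probes rose and 12 fell after TCPOBOP (limma, Benjamini-Hochberg adjusted p under 0.05). Mm038 and Mm039 had the highest log2 ratios. Mm038 was on average at least 17.3-fold higher in treated livers than in the pool (adjusted p = 3.21e-07). Mm038 was lowest on WT 1, at a log2 ratio of 1.91. Its Cy3 signal was not well above background on any of the 6 arrays, and the bound is open to dye bias. Mm039 rose with a log2 ratio of 4.19 ± 1.30 (n = 6, adjusted p = 2.55e-08). Its Cy3 signal was well above background on 1 of the 6 arrays, so this value is no measured fold. Which of Mm038 and Mm039 rose more was not measured. Both were above 0 on 6 of 6 arrays. The largest falls were those of Mm061 (−0.89 ± 1.05, below 0 on 5 of 6 arrays, adjusted p = 0.0119) and Mm044 (−0.64 ± 0.28, below 0 on 6 of 6, adjusted p = 1.28e-04). The median change was 0.67 among the probes that rose and −0.41 among those that fell. Without WT 6 the fall of Mm061 was −0.54 and no longer passed the threshold (adjusted p = 0.0727), and its call also ended when only the WT arrays were fitted and without the 4 arrays with conflicting protocol text (adjusted p = 0.0768 and 0.1117). Centred on the calibration control spots, the median of all probes was −0.37 and the calls were 4 rises and 11 falls. The authors' value table, in which neither Mm038 nor Mm039 had enough values to be tested, gave 2 rises and 13 falls. Its medians over mouse probes were −1.02 to −0.85 on WT 1 to 4 and 0.64 and 0.65 on WT 6 and WT 5. Its calibration control medians were −0.12 to 0.025 on all 6, so centring on those spots does not account for this split. Slide position was examined after the data had been seen: the upper position gave 4 probes, without Mm061 (−0.43, adjusted p = 0.4579), the lower 20, and position as a block 33.

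**Figure D1:**
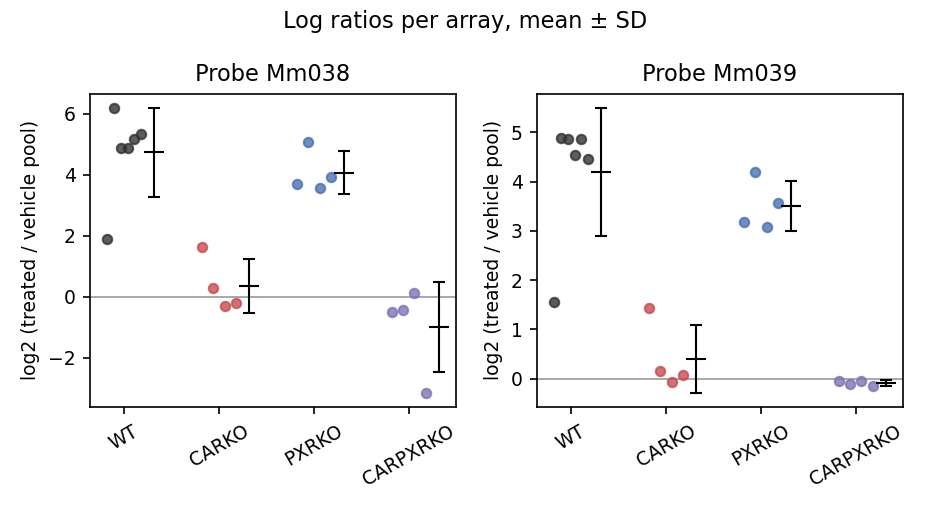
Log2 ratios of treated liver over vehicle pool for probes Mm038 and Mm039 (vertical axes) on each array, by genotype (horizontal axes), with arrays as points and the mean ± SD as bars. For Mm038, whose Cy3 signal was near background throughout, the 6 WT arrays lie between 1.91 and 6.20 and the 4 PXRKO arrays between 3.57 and 5.10.

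In CAR-deficient livers 3 of 82 probes rose and 1 fell. Mm054 rose with a log2 ratio of 0.59 ± 0.44 (n = 6, above 0 on 5 of 6 arrays, adjusted p = 0.0085), and Mm092 with 0.53 ± 0.22 (6 of 6, adjusted p = 0.0156). The mean of Mm092 was also above 0 in WT (0.68), PXRKO (0.42) and CARPXRKO (0.23). Mm092 was well above background in Cy3 on 0 of 4 arrays in PXRKO and in CARPXRKO, so the means there are no measured ratios. Its difference of CARKO minus WT was −0.16 (limma, adjusted p = 0.5499), so a dye bias of this probe cannot be told apart from a response. Mm062 fell, with −0.35 ± 0.29 (below 0 on 6 of 6, adjusted p = 0.0257). Centred on the calibration control spots, Mm062 was at 0.0065 (adjusted p = 0.9806). Mm038 was well above background in Cy5 on 1 of the 6 arrays and Mm039 on 2, and neither passed the threshold (adjusted p = 0.76 and 0.66). Both had a value on 4 of the 6 arrays. On CARKO 1 alone the ratios of these probes were 1.62 and 1.43. The count fell to 2 without CARKO 3, to 0 without CARKO 4 (6 probes at an unadjusted p under 0.05 in limma) and to 2 without CARKO 6. The calls of Mm054, Mm092 and Mm062 ended without CARKO 4, with adjusted p = 0.0577, 0.1033 and 0.2015; that of Mm062 ended without CARKO 3 or CARKO 6 as well. When only the CARKO arrays were fitted the calls of Mm054 and Mm062 ended (adjusted p = 0.2159 for each), with trended and robust eBayes that of Mm092 (adjusted p = 0.0729), and without the 4 arrays with conflicting protocol text that of Mm062 (adjusted p = 0.1421), and without CARKO 1 and CARKO 5 that of Mm092 (adjusted p = 0.0581). The upper slide position gave 0 probes in limma (5 at an unadjusted p under 0.05), the lower 1, without Mm092 or Mm062 (adjusted p = 0.0761 and 0.1142), and position as a block 4. Rises and falls numbered 2 and 0 with median centring, 3 and 2 with print-tip loess, 5 and 5 with scale normalization, and 0 and 0 in limma on the calibration-centred values (median of all probes 0.35) and on the authors' table, with 12 and 2 probes at an unadjusted p under 0.05.

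Across the 2 genotypes the difference itself was tested: the responses of 6 probes were higher and those of 9 lower in CARKO than in WT. Mm038 and Mm039 gave the largest differences, of −4.39 ± 0.72 and −3.79 ± 0.51 on the log2 scale (SE, adjusted p = 2.32e-04 and 8.73e-05). These differences rest on Cy3 signals near background and are no measured folds. In CARKO both probes had a value on 4 of the 6 arrays, CARKO 1 among them, and Cy5 was well above background on 1 and 2 arrays. All 9 probes that were lower in CARKO were among the 20 that rose in WT, where independent lists would share 2.20. These lists use the same WT arrays. Simulated unchanged groups shared 0, but had on average 0.01 calls per list, so this value does not show what the shared arrays add when WT responds. When the response was taken from the odd WT replicates and the difference from the even ones, 7 probes were shared (lists of 9 and 10). The other way round 6 were shared (lists of 18 and 6). Odd and even replicates also lie in different slide positions. All WT arrays share 1 pool, so the split cannot remove an error of that pool, which would enter both lists. The lists are not independent, and none of these values is the effect of the shared arrays alone. Mm044, which fell in WT, was higher in CARKO by 0.56 ± 0.15 (SE, adjusted p = 0.0127), and Mm013 by 0.53 ± 0.15 (SE, adjusted p = 0.0136). Mm013 was well above background in Cy5 on 1 of the 6 WT arrays. Its call ended with background subtraction (adjusted p = 0.1308), with median centring (difference 0.24, adjusted p = 0.4280) and without the 4 arrays with conflicting protocol text (adjusted p = 0.0809). That of Mm044 ended without those 4 arrays (adjusted p = 0.0942), in the authors' table (adjusted p = 0.2464) and with the probes that rose in WT at weight 0 in the loess (adjusted p = 0.1049). No probe passed the threshold among the arrays in the upper position (limma, 11 at an unadjusted p under 0.05), 7 did among those in the lower position, without Mm044 or Mm013 (adjusted p = 0.1492 and 0.2161), and 15 did with position as a block; Mm038 and Mm039 had too few values to be tested within a position. With calibration centring, where the median of all probes was 0.73, 20 probes were higher and 3 lower; the authors' table gave 1 and 0.

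In PXR-deficient livers 10 of 82 probes rose and 5 fell. Mm038 was on average at least 15.8-fold higher in treated livers than in the pool (adjusted p = 4.65e-05). Its Cy3 signal was not well above background on any of the 4 arrays. Mm039 rose with a log2 ratio of 3.50 ± 0.51 (n = 4, above 0 on 4 of 4 arrays, adjusted p = 7.81e-06). Its Cy3 signal was well above background on 1 of the 4, so this value is no measured fold. Mm001 had the largest fall, −1.34 ± 1.46, below 0 on 3 of 4 arrays (adjusted p = 0.0218), and Mm150 fell with −0.68 ± 0.53, also on 3 of 4 (adjusted p = 0.0162). Of the 20 probes that rose in WT, 8 rose in PXRKO, where independent lists would share 2.44 (two-sided Fisher's exact test, p = 1.16e-04, adjusted p = 0.0014 over 12 such overlaps). Across the 82 probes the mean responses of WT and PXRKO had a Pearson correlation of 0.90 and a Spearman correlation of 0.57; without Mm038 and Mm039 the Pearson correlation was 0.68. Probes are not independent replicates, and a dye bias shared by the arrays would add to these values. The count was 6 without PXRKO 1, 25 without PXRKO 2, 6 without PXRKO 3 and 7 without PXRKO 4, and the calls of Mm001 and Mm150 ended without PXRKO 1, 3 or 4 (highest adjusted p = 0.1438 and 0.1099). Without PXRKO 2, where Mm001 was at 0.82 against −2.37 to −1.79 on the other arrays, its fall was −2.06. Both calls ended with median centring (adjusted p = 0.0501 and 0.3088), in the authors' table (adjusted p = 0.1805 and 0.8730) and when only the PXRKO arrays were fitted (adjusted p = 0.2128 and 0.1347); that of Mm001 ended without the 4 arrays with conflicting protocol text (adjusted p = 0.0539), and that of Mm150 with the probes that rose in WT at weight 0 in the loess (adjusted p = 0.0591). Arrays in the upper slide position gave 9 probes, the lower 0 in limma (8 at an unadjusted p under 0.05, Mm001 at −0.61 and Mm150 at −0.38), and position as a block 17. The calls were 9 rises and 0 falls with calibration centring (median of all probes 0.35), and 3 and 0 in the authors' table. With calibration centring Mm150 changed sign, to 0.11 (adjusted p = 0.7881), and Mm001 was at −0.68 (adjusted p = 0.3420).

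The response differed between PXRKO and WT for 3 probes, 1 higher and 2 lower in PXRKO. Chance cannot be excluded for this count, as 6 of 100 splits of the same arrays gave at least as many. Mm018 was lower by a log2 difference of −0.94 ± 0.18 (SE, adjusted p = 0.0041): its ratio was 0.65 ± 0.33 in WT (n = 6, above 0 on 6 of 6 arrays) and −0.29 ± 0.40 in PXRKO (n = 4, above 0 on 1 of 4). Mm068 was lower by −0.80 ± 0.19 (SE, adjusted p = 0.0161), and Mm044 was higher by 0.67 ± 0.17 (SE, adjusted p = 0.0260). The count was 5 without WT 3, 5 without WT 5, 13 without PXRKO 2, 1 without PXRKO 3 and 1 without PXRKO 4; the call of Mm068 ended without PXRKO 3 or 4 and that of Mm044 without WT 1, WT 2, PXRKO 1, PXRKO 3 or PXRKO 4 (highest adjusted p = 0.0713 and 0.1474). The call of Mm044 ended with scale normalization (0.58, adjusted p = 0.1453). It ended at about the reported difference when only the PXRKO and WT arrays were fitted (0.67, adjusted p = 0.0904). Without the 4 arrays with conflicting protocol text it ended likewise (0.69, adjusted p = 0.0708). Higher and lower probes numbered 8 and 0 with calibration centring, where the median of all probes was 0.75 and Mm018 and Mm068 had differences of 0.052 and −0.17, and 0 and 2 with scale normalization; median centring gave 15 probes in place of 3. Limma on the authors' table gave 0 and 0, with 14 probes at an unadjusted p under 0.05. Within the upper and the lower slide position limma gave 0 probes each, with 14 and 9 at an unadjusted p under 0.05, and 3 with position as a block.

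In livers deficient in both receptors 10 of 82 probes rose and 7 fell. The largest rises were those of Mm066 (0.65 ± 0.15, n = 4) and Mm062 (0.62 ± 0.17, n = 4), both above 0 on 4 of 4 arrays (adjusted p = 0.0035 and 0.0024). Both calls ended with calibration centring, at 0.36 and 0.50 (adjusted p = 0.5311 and 0.3250). In the authors' table they ended as well, at 0.28 and 0.44 (adjusted p = 0.6413 and 0.4484). The largest falls were those of Mm007 (−0.57 ± 0.21) and Mm054 (−0.54 ± 0.13), both below 0 on 4 of 4 arrays (adjusted p = 0.0141 for each). Mm038 and Mm039 did not pass the threshold (adjusted p = 0.26 and 0.92), and Mm038 was well above background in Cy5 on 1 of the 4 arrays. Of the 12 probes that fell in WT, 4 rose in CARPXRKO, where independent lists would share 1.46 (two-sided Fisher's exact test, p = 0.0352, adjusted p = 0.2114). Of the 20 that rose in WT, 2 rose and 3 fell. Across probes the WT and CARPXRKO mean responses had a Pearson correlation of −0.41, and −0.36 without Mm038 and Mm039; single arrays of these genotypes correlated between −0.61 and 0.08. The labels state the dyes and the pools differed, so the direction was kept. The count was 11 without CARPXRKO 1, 10 without CARPXRKO 3 and 9 without CARPXRKO 4. The call of Mm007 ended without CARPXRKO 1 or 2 and that of Mm054 without CARPXRKO 3 or 4 (highest adjusted p = 0.0685 and 0.0717). The call of Mm007 ended with median centring (−0.44, adjusted p = 0.1687). It also ended, though the fall was larger, with calibration centring (−0.83, adjusted p = 0.1918) and in the authors' table (−0.76, adjusted p = 0.2001). That of Mm054 ended with calibration centring, where its fall was larger (−0.94, adjusted p = 0.0528). It ended without the 4 arrays with conflicting protocol text as well (−0.54, adjusted p = 0.0705). Among arrays in the upper slide position 2 probes passed, without Mm062, Mm007 or Mm054 (adjusted p = 0.0517, 0.2819 and 0.3181); the lower gave 0 in limma (17 at an unadjusted p under 0.05), and position as a block 16. Rises and falls numbered 13 and 5 with median centring, 0 and 5 with calibration centring (median of all probes −0.34) and 0 and 6 in the authors' table.

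**Figure D2:**
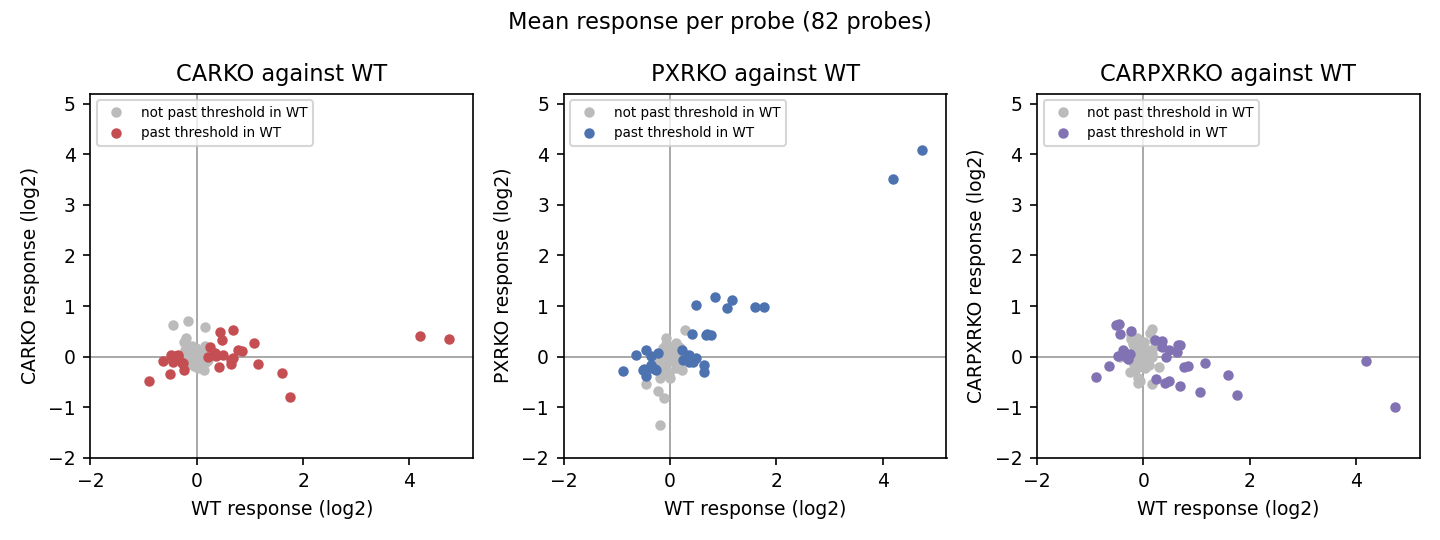
Mean log2 response of each of the 82 tested probes in CARKO, PXRKO and CARPXRKO (vertical axes) against its mean response in WT (horizontal axes), with probes as points. Mm038 and Mm039 lie at 4.74 and 4.19 in WT and at 4.08 and 3.50 in PXRKO, values measured against Cy3 signals near background, and across probes the Pearson correlation with WT was 0.15 for CARKO, 0.90 for PXRKO and −0.41 for CARPXRKO.

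Against wild type, the CARPXRKO response was higher for 9 probes and lower for 15. Mm062 was higher by 1.12 ± 0.15 and Mm066 by 1.10 ± 0.17 on the log2 scale (SE, adjusted p = 1.01e-05 and 7.70e-05). The Mm062 ratio was −0.51 ± 0.22 in WT and 0.62 ± 0.17 in CARPXRKO. Mm038 and Mm039 were the lowest, with differences of −5.72 ± 0.72 and −4.28 ± 0.51 (SE, adjusted p = 1.01e-05 for each) that again rest on Cy3 near background; without CARPXRKO 4 the difference of Mm038 was −5.00. Of the 20 probes that rose in WT, 13 were lower in CARPXRKO than in WT, and of the 12 that fell, 8 were higher; independent lists would share 3.66 and 1.32. Simulated unchanged groups shared 0, but had at most 0.03 calls per list on average, which sets no level for lists that share a responding WT group. With the WT arrays split between both lists, 7 or 8 of the former were shared (lists of 9 and 16, or 18 and 11). Of the latter 2 or 4 were shared (lists of 4 and 7, or 9 and 7). The 9 probes lower in CARKO than in WT and the 15 lower in CARPXRKO than in WT had 8 in common, against 1.65 for independent lists; the simulated 0 rests on as few calls. With the WT arrays split, 5 or 7 were shared (lists of 6 and 16, or 10 and 11). All these splits leave the WT pool shared, so they cannot remove an error of that pool. Higher and lower probes numbered 21 and 17 with median centring, 1 and 3 with calibration centring (median of all probes −0.08), and 0 and 0 in limma on the authors' table, with 13 at an unadjusted p under 0.05. In these last fits the differences of Mm062 were 1.52 (adjusted p = 0.0229) and 1.45 (adjusted p = 0.0584), and those of Mm066 1.34 (adjusted p = 0.0517) and 1.25 (adjusted p = 0.0584). The upper slide position gave 3 probes, the lower 17, and position as a block 24.

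**Figure D3:**
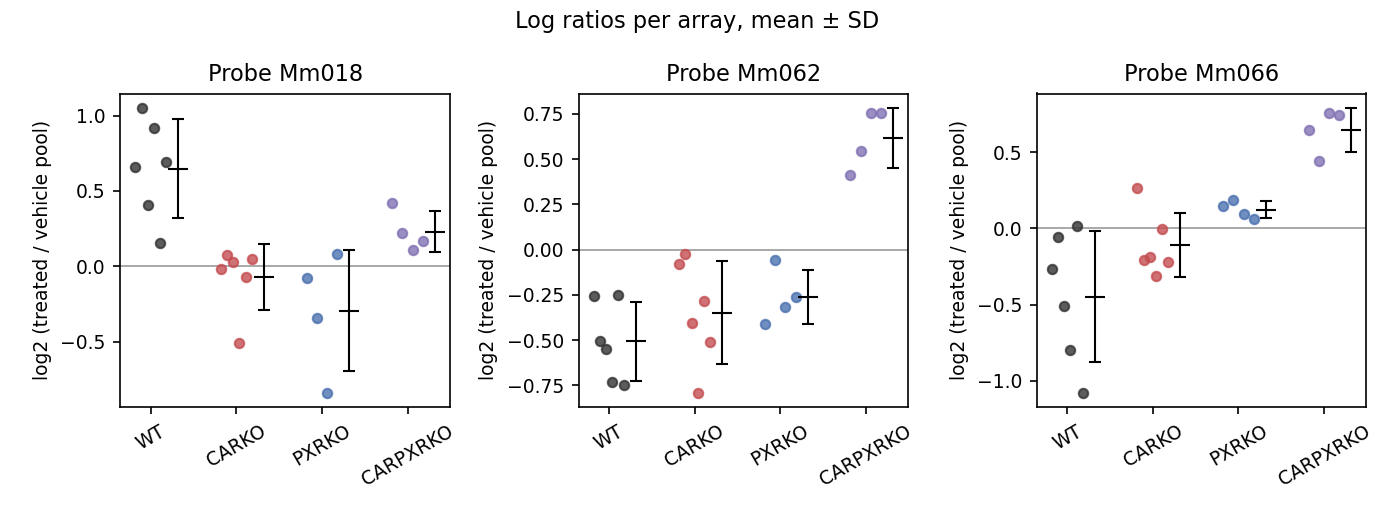
Log2 ratios of treated liver over vehicle pool for probes Mm018, Mm062 and Mm066 (vertical axes) on each array, by genotype (horizontal axes), with arrays as points and the mean ± SD as bars. Mm062 lies below 0 on 6 of 6 WT arrays and above 0 on 4 of 4 CARPXRKO arrays.

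Loss of PXR in addition to CAR was examined as CARPXRKO against CARKO, with 10 probes higher and 8 lower. Each genotype had 1 pool, so a difference between the CARPXRKO and CARKO pools cannot be told apart from this loss. Mm062 was higher by 0.97 ± 0.15 and Mm073 by 0.77 ± 0.14 (SE, adjusted p = 2.02e-04 and 8.89e-04). Mm073 was well above background in Cy3 on 1 of the 4 CARPXRKO arrays, so its difference is no measured fold. Mm054, which rose in CARKO and fell in CARPXRKO, was lower by −1.14 ± 0.19 (SE, adjusted p = 4.21e-04), and Mm037 was lower by −0.96 ± 0.34 (SE, adjusted p = 0.0479). Leaving out 14 of the 20 arrays, each alone, ended the call of Mm037 (highest adjusted p = 0.2102, difference −0.74 without CARPXRKO 4), and it ended under 11 of 20 other settings (highest adjusted p = 0.5717). Those of Mm062 and Mm073 ended with calibration centring (adjusted p = 0.3581 and 0.9131) and in the authors' table (adjusted p = 0.3742 and 0.8970). Higher and lower probes numbered 8 and 4 with median centring, 0 and 19 with calibration centring (median of all probes −0.68, Mm073 at −0.05) and 0 and 1 in the authors' table. The upper slide position gave 0 probes in limma (11 at an unadjusted p under 0.05), the lower 14, and position as a block 17.

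Loss of CAR in addition to PXR was examined as CARPXRKO against PXRKO, with 11 probes higher and 12 lower. Here too, a difference between the single pools of both genotypes cannot be told apart from this loss. Mm038 and Mm039 were lower by −5.07 ± 0.79 and −3.59 ± 0.56 (SE, adjusted p = 2.83e-04 for each). Cy3 of Mm038 was well above background on 0 of 4 arrays in either genotype and that of Mm039 on 1 of 4 in each, so these are no measured folds, and without CARPXRKO 4 the difference of Mm038 was −4.35. Mm001 was higher by 1.60 ± 0.57 and Mm150 by 1.03 ± 0.26 (SE, adjusted p = 0.0456 and 0.0073). Of the 20 probes that rose in WT, 10 were lower in CARPXRKO than in PXRKO and 1 was higher. The count was 13 without PXRKO 3 and 15 without CARPXRKO 3, and the call of Mm001 ended in 11 of the 20 fits that left out 1 array (highest adjusted p = 0.1380, difference 1.26 without PXRKO 1) and under 12 of 20 other settings (highest adjusted p = 0.4449); without PXRKO 2, where Mm001 was at 0.82, its difference was 2.32. The call of Mm150 ended with median centring (adjusted p = 0.0548), with calibration centring (adjusted p = 0.7707) and in the authors' table (adjusted p = 0.5619). Higher and lower probes numbered 4 and 12 with median centring, 4 and 12 with scale normalization, 0 and 13 with calibration centring (median of all probes −0.72) and 0 and 4 in the authors' table. The upper slide position gave 5 probes, the lower 3, without Mm150 (adjusted p = 0.2234), and position as a block 21.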

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

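The tests of a wild type liver under the CARKO label, of signal at background, of an exchange of samples, of slide position, of the calls that ended under the other loess, and of the size of these differences under other centrings, were chosen only after the values were seen.

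The probes named for the differences between genotypes were picked by passing the test of that difference, so their passing adds no support. The limits given above hold for the values listed here. Those of Mm038 and Mm039 rest on Cy3 near background. The calls of Mm037 and Mm001 ended in 14 and 11 of the 20 fits that left out 1 array. The log2 differences of CARKO minus WT were 0.56 for Mm044, 0.53 for Mm013, −4.39 for Mm038 and −3.79 for Mm039. Those of PXRKO minus WT were 0.67 for Mm044, −0.94 for Mm018 and −0.80 for Mm068. Those of CARPXRKO minus WT were 1.12 for Mm062, 1.10 for Mm066, −5.72 for Mm038 and −4.28 for Mm039. Those of CARPXRKO minus CARKO were 0.97 for Mm062, 0.77 for Mm073, −1.14 for Mm054 and −0.96 for Mm037. Those of CARPXRKO minus PXRKO were 1.60 for Mm001, 1.03 for Mm150, −5.07 for Mm038 and −3.59 for Mm039.

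Other groupings of the same arrays tested whether a chance assignment of single arrays could give each count. For CARKO minus WT, 1 of 100 splits, the real one, gave as many as 15 probes (highest other 7); for CARPXRKO minus WT 1 of 100 gave 24 (highest other 17); for CARPXRKO minus CARKO 1 of 100 gave 18 (highest other 5); and for CARPXRKO minus PXRKO 1 of 35 gave 23 (highest other 7). For these counts the splits argue against a chance assignment of single arrays. Each set of 100 held the real split and a random draw of the others. There were 462 possible splits for CARKO minus WT and 210 for each other comparison with 100. For CARPXRKO minus PXRKO all 35 possible splits were used. The highest other counts therefore hold for the splits drawn. In each case the real split alone is the smallest share these splits can give. The splits cannot test the make-up of a pool, because all arrays of a genotype share 1 pool and it favours the real split. For PXRKO minus WT, 6 of 100 splits gave at least the 3 probes observed (highest other 8), so chance cannot be excluded.

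Of 64 sets, each holding the values of 1 named probe in 1 genotype, 11 held an array far from the others. Independent sets would give about 1 in 20, or 3.20. These sets share the same arrays and the probes were picked by their calls, so 3.20 is no fair chance level. On WT 1 the log2 ratios of Mm038 and Mm039 were 1.91 and 1.56, below the next WT array at 4.89 and 4.46. CARKO 5 stood apart for Mm001 (2.54), Mm007 (−0.79), Mm068 (0.59) and Mm150 (1.06). The other such values were 0.55 for Mm001 on CARPXRKO 2, −0.51 for Mm018 on CARKO 4, 0.42 for Mm037 on PXRKO 2, 1.43 for Mm039 on CARKO 1 and −0.25 for Mm044 on CARPXRKO 3.

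CARKO 1 had ratios of 1.62 and 1.43 for Mm038 and Mm039, against at most 0.30 and 0.16 on the other 3 CARKO arrays with a value. All 6 Cy5 spots of these probes on CARKO 1 lay above background, which argues against noise in Cy5 alone, but 0 of the 6 Cy3 spots did, so noise in the Cy3 signal stays open as a part of both ratios. The other 18 probes that rose in WT had a median of −0.016 on CARKO 1, below the lowest WT array (0.32), which argues against a wild type liver under this label as far as the pools of both genotypes hold similar levels. Carry-over of RNA from a liver that induced both probes stays open, because the share it needs rests on Mm039 against Cy3 at background and is not measured, and the median rise of those 18 probes over the other CARKO arrays, 0.048, is small against their spread (SD 0.36). A response of this animal without CAR is a further open explanation and was not tested.

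The 9 probes higher in CARPXRKO than in WT included 8 that had fallen in WT. With the probes that rose in WT at weight 0 in the loess, 5 of the 9 still passed the threshold, exactly the number set beforehand as the least that would argue against the curve, and all 9 stayed above 0, which argues against a bent curve as the whole cause for these 5 only. A part from the curve stays open for all 9, whose median difference moved from 0.65 to 0.38, and for the 4 whose call ended it moved from 0.47 to 0.24 (median SE 0.14 after in both). All 9 stayed above 0 and passed with median centring, while 1 passed with calibration centring (median 0.79, median SE 0.42). In the values of the authors, whose mouse-probe medians split within WT, 0 passed (0.61, SE 0.39). Under both of these settings calls ended with an SE that rose from 0.15, while the median differences stayed close to the reported 0.65. At least 7 passed whichever CARPXRKO array was left out, which argues against a lone array, while the make-up of the only CARPXRKO pool cannot be told apart from genotype (Cy3 level 0.15 above the WT pool, Cy5 level 0.99 above), because all 4 arrays share it, and an effect of losing both receptors stays open beside it.

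CARKO 5 and PXRKO 2 departed from their group means alike, with a correlation of 0.78 across probes, the highest of 148 pairs of arrays of different genotype (next 0.62), and 0.60 without the 5 probes that departed most. An exchange of these samples is argued against by Mm039, at 4.20 on PXRKO 2 and at most 1.43 on the 4 CARKO arrays with a value, which do not include CARKO 5, so only the PXRKO 2 side of an exchange was tested. The arrays lie in different slide positions (CARKO 5 upper, PXRKO 2 lower), so a shared position cannot make them alike, and the median correlation of −0.23 between CARKO 5 and the 7 arrays of other genotypes in its own position decides nothing about this pair. No biological explanation was tested, since the labels give none that both mice share.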

How the results depend on the processing

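The settings keeping flagged spots, using slide position or an inferred slide, leaving out CARKO 1 and CARKO 5, or giving the probes that rose in WT weight 0 in the loess were chosen after seeing the data. Counts below run in the order WT, CARKO, PXRKO, CARPXRKO, CARKO minus WT, PXRKO minus WT, CARPXRKO minus WT, CARPXRKO minus CARKO and CARPXRKO minus PXRKO, with 32, 4, 15, 17, 15, 3, 24, 18 and 23 probes past the threshold as reported; only counts that moved by over 1.5 times are given. With a fold of at least 1.5 required as well, WT had 14, CARKO 1, CARPXRKO 2, CARKO minus WT 9 and CARPXRKO minus CARKO 11. Background subtraction gave 24 for CARKO minus WT and 8 for PXRKO minus WT. Median centring gave 2 for CARKO, 15 for PXRKO minus WT and 38 for CARPXRKO minus WT; print-tip loess gave 6 for PXRKO minus WT and scale normalization 10 for CARKO. Loess through the calibration controls gave 15, 0, 9 and 5 for the responses in order, 23 for CARKO minus WT, 8 for PXRKO minus WT, 4 for CARPXRKO minus WT and 13 for CARPXRKO minus PXRKO. The authors' table, with 68 probes tested, gave 15, 0, 3, 6, 1, 0, 0, 1 and 4. Array weights, with the lowest weight at CARKO 5 (0.23), gave 17 for CARKO, 33 for PXRKO, 28 for CARPXRKO and 29, 16, 37, 31 and 40 for the differences. Only the arrays of the groups compared gave 1 for CARKO, 7 for PXRKO and 29 for CARPXRKO. Without the 4 arrays with conflicting protocol text there were 2 for CARKO, 8 for CARPXRKO, 8 for CARKO minus WT, 10 for CARPXRKO minus CARKO and 13 for CARPXRKO minus PXRKO. Keeping flagged spots, with 120 probes tested, gave 35 for CARPXRKO, 6 for PXRKO minus WT, 40 for CARPXRKO minus WT and 28 for CARPXRKO minus CARKO. The upper slide position alone gave 4, 0, 9, 2, 0, 0, 3, 0 and 5, and the lower 20, 1, 0, 0 and 7 for the first 5, 0 for PXRKO minus WT and 3 for CARPXRKO minus PXRKO, with fewer arrays in each. At the responses with 0 probes, limma gave 5 (CARKO, upper), 8 (PXRKO, lower) and 17 (CARPXRKO, lower) at an unadjusted p under 0.05. With the probes that rose in WT at weight 0 in the loess, PXRKO minus WT had 6. The cause of these moves was not tested. The filter on dim probes removed no tested probe and decides nothing. With each array left out in turn the counts ranged from 26 to 34, 0 to 5, 6 to 25, 9 to 20, 12 to 21, 1 to 13, 21 to 28, 13 to 19 and 13 to 34.

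With the replicate block the differences had 18, 3, 23, 17 and 23 probes past the threshold, within 1.5 times the reported counts. Same-numbered arrays did not deviate together in every pair (the correlations for WT and CARKO ranged from −0.50 to 0.17). Their median correlation lay above that of the other arrays, most clearly for WT and CARKO (0.15 against −0.005). Only PXRKO and CARPXRKO went the other way (−0.03 against 0.01). Of 20 arrays, 1 correlated best with its own number. Odd and even numbers mark the slide position, and so few pairs cannot exclude that a number marks more. The block ended the call of Mm037 in CARPXRKO minus CARKO. Among 633 values of the 34 named probe results under settings other than leaving out an array, 525 stayed past the threshold in the same direction, 104 no longer passed it and 4 changed sign. All 4 changed sign with loess through the calibration controls, to 0.0065 for Mm062 in CARKO, 0.11 for Mm150 in PXRKO, 0.052 for Mm018 in PXRKO minus WT and −0.048 for Mm073 in CARPXRKO minus CARKO; the cause was not tested. Mm038 and Mm039 kept their direction and passed the threshold in WT and PXRKO and in the differences from them under every setting in which they were tested; the authors' table and the fits within a slide position held too few of their values. Their Cy3 signal near background limits the size of their changes, not their direction. No slide or scan date is used here, and the camera tests, the mean over probes of a gene and the other normalization of the knocked-out genes were not run.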

Other observations

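Of the 82 probes, 46 passed the threshold in at least 1 genotype and 36 in none. None rose in all 4 genotypes. Of the 20 that rose in WT, the response of 13 was lower in CARPXRKO than in WT. In CARKO 9 were lower and in PXRKO 2, and 1 was lower in all 3. These lists share the WT arrays and their pool. The 20 had a median log2 ratio of 0.67 in WT, 0.06 in CARKO, 0.44 in PXRKO and −0.16 in CARPXRKO, where the WT value is raised by the choice of probes in the same arrays. The 12 that fell in WT had medians of −0.41, −0.10, −0.24 and 0.07.

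The mean response had the same sign in all 4 genotypes for 11 of 82 probes, where independent signs would give 10.2. Of the 4 probes called in CARKO, 3 were called in WT with the same sign. Within genotypes, pairs of arrays correlated across probes with a median of 0.90 in WT, 0.17 in CARKO, 0.70 in PXRKO and 0.59 in CARPXRKO. CARKO 1 correlated with the WT arrays at 0.37 to 0.70, with Mm038 and Mm039 included. The unnormalized median log2 ratio of the mouse spots ranged from −2.24 to −0.31 on WT arrays and from −0.14 to 0.29 on CARPXRKO arrays.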
